A study of Mus musculus with 12 samples.

How the data were processed

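RNA sequencing of mouse embryonic stem cells was analysed in 12 libraries. Per the labels, the cells were clones 4 and 10 derived from mice with a floxed Sphk1 and no Sphk2, treated with 6 uM 4-hydroxytamoxifen for 48 hours and sorted by the green fluorescence of Cre-GFP. Each clone gave 3 GFP-negative and 3 GFP-positive libraries, 4 groups in all. RNA was total RNA taken through a TruSeq v2 library kit. Passage numbers ran from 11 to 20 and differed between replicates. Those of replicates 2 and 3 rose by 1 from each sample to the next across clones and gates, so their accuracy is uncertain. In 5 of 6 pairs of the same clone and replicate number, the GFP-positive library was labelled 1 passage later than its partner, so in those pairs a passage goes with the gate. Nothing in the labels says whether the replicates were separate cultures or sorts, so the p-values measure the spread between these libraries, part of which may be technical.

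The deposited count table holds whole-number read counts per gene that the authors did not normalize. STAR 2.3.0e, HTSeq 0.6.0, DESeq2, DESeq and the mm10 build are named in the submitters' processing notes. The annotation release and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. A deposited table per clone compares GFP-positive with GFP-negative cells. Per the file headers, these tables hold the counts, a signal per library and its mean (the counts divided by a size factor of the library), a log2 fold change with its standard error, a score (the fold change over its standard error) and p-values before and after adjustment. The authors' log2 fold changes were smaller than the log2 ratios of their normalized means, as shrinkage toward 0 would give, and were set beside the values fitted here only with that source named. Every count column in these tables was identical to the count table, with 0 columns differing. The table lists 22753 genes, of which 22740 are annotated as protein-coding and 13 as polymorphic pseudogenes. Symbols and mm10 coordinates were taken from the authors' tables.

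Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood F test, TMM normalization, limma 3.58.1 for gene lists). The default filter on low counts asked for a level worth 10 counts at the median library size in at least 3 libraries of any group. It also asked for 15 counts in total. This left 15179 genes, and 7574 were not tested. All 12 libraries entered a single fit with a term per group, which left 8 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Every adjusted p for a gene comes from this test unless another is named. Fold changes are on the log2 scale with their standard error (SE), and levels are in CPM, the read count scaled by the total count of the library, while log2 CPM values use the effective library size of the TMM normalization.

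The replicate numbers of the labels pair GFP-positive with GFP-negative libraries within a clone. The deviations from the group means of the 6 same-numbered pairs correlated at 0.548 to 0.822, and those of differently numbered libraries of a clone at -0.541 to -0.228. Between the clones, libraries numbered 1 correlated at 0.399 to 0.588 and those numbered 2 and 3 crosswise at 0.387 to 0.683, whereas 2 with 2 and 3 with 3 gave -0.425 to -0.0714. Libraries of the clones thus varied together in a way that the labels do not explain. A second fit therefore held the pair as a block, with 4 residual degrees of freedom, and its values are called within pairs. The biological coefficient of variation was 0.389 without the block and 0.175 within pairs. The fit without the block was the planned one. The block was planned as an alternative to it before the data were examined. Its use as a second fit throughout the results followed the correlations given here.

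Gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with adjustment over the 32 lists that had at least 3 measured members. Camera with a correlation estimated from the data and fry were run beside it. None of the calls by camera held with the estimated correlation in any comparison or fit. Members of a list were also counted with p-values adjusted over the list alone.

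Genes to be named were chosen by a rule written before the data were examined. For the mean of both clones it took the 10 largest rises and 10 largest falls among called genes with an average log2 CPM of at least 1 and the same sign in both clones. For each clone it took the 8 largest of each direction whose GFP-positive and GFP-negative libraries did not overlap, and for the clones against each other the 5 largest of each direction. Sphk1 and Sphk2 were always named, with up to 4 members of a list by smallest p, and predicted or clone names were passed over in the rankings but counted. The rule was applied to the fit within pairs after the data were seen. A few other genes were chosen after their values were seen, and are named as such. The result of one gene that the rule selected is not reported here.

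The tests were run on simulated counts drawn from the libraries' own means and spread, with 100 genes changed by 2-fold and 100 by 8-fold. With the spread of the fit without the block and no pairs simulated, 14966 genes were tested. That fit recovered 39% of the 2-fold and 100% of the 8-fold changes for the mean of both clones, 7% and 91% for clone 4, and 5% and 84% for clone 10. With levels per pair simulated, 14889 genes were tested. There the fit without the block recovered 34% and 96% for the mean, 1% and 86% for clone 4, and 6% and 85% for clone 10. The fit within pairs recovered 91% and 100% for the mean, 72% and 100% for clone 4, and 79% and 99% for clone 10, and called 6, 8 and 14 unchanged genes. The simulated difference between clones was 0 for every gene and gave 0 calls. Each simulated change was the same in all pairs, so the shares recovered may be too high where real changes vary between pairs. The fit without the block called 0 genes in each real clone, although its medians for the two-cell-like list were 3.22 and 3.93.

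Alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2 size factors, no filter and a stricter filter (1 CPM in 6 libraries), passage as a covariate, only the libraries of a comparison, a minimum change of 2-fold, the pair block and the removal of each library in turn. The same changes to the fit within pairs, the removal of each pair and a covariate for fibroblast markers were added after the data were seen. Sequence uniqueness and GC content were taken from the transcripts of GENCODE release M21. Figures were drawn with matplotlib 3.10.9. Libraries of a group were not duplicates of each other, since their counts differed by 34.2 to 249 times the sampling variance. Total counts ran from 12968916 to 34258395 per library, which leaves genes near 1 CPM with few reads.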

Results

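Gene expression was measured by RNA sequencing in mouse embryonic stem cells whose sphingosine kinase genes, the enzymes that make sphingosine 1-phosphate, were Sphk1 floxed and Sphk2 null. Clones 4 and 10 were treated with 4-hydroxytamoxifen and sorted into GFP-negative cells, labelled as keeping the floxed Sphk1, and Cre-GFP-positive cells, labelled as null for both kinases, with 3 libraries in each of the 4 groups. In clone 4, GFP-negative replicates 1 to 3 held 21935860, 19196623 and 24710535 counts and GFP-positive replicates 20798307, 20655269 and 34258395. In clone 10, GFP-negative replicates held 12968916, 32614087 and 20948701 counts and GFP-positive replicates 19112398, 33215399 and 20285761. The shallowest library, clone 10 GFP-negative replicate 1, also had the lowest share of counts in mitochondrial genes (0.143%) and the highest share in its top 10 genes (7.39%). The mitochondrial share was higher in the GFP-positive library of each of the 6 pairs, at 0.851% against 0.594%, 0.896% against 0.845% and 2.21% against 1.43% in clone 4 and at 0.849% against 0.143%, 2.32% against 2.11% and 1.22% against 1.03% in clone 10, so this measure of library composition goes with the gate. Libraries of the same clone and replicate number varied together, so GFP-positive and GFP-negative cells were compared both across all libraries and within the 6 pairs.

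Sphk1 (ENSMUSG00000061878, mm10 chromosome 11, 116530925 to 116536674) was detected at a low level in every library. In clone 4 it stood at 2.25 ± 0.67 CPM in GFP-negative and 1.26 ± 0.68 CPM in GFP-positive cells (SD, n = 3 each), and in clone 10 at 2.13 ± 1.91 and 1.68 ± 1.16 CPM. The log2 change in GFP-positive cells was -0.84 (SE 0.65) in clone 4, -0.42 (SE 0.64) in clone 10 and -0.63 over both clones (95% confidence interval -1.62 to 0.37, adjusted p = 0.767), within the spread between libraries. Within pairs it was -0.61 (SE 0.25, interval -1.17 to -0.05, adjusted p = 0.166), with lower values in 4 of 6 pairs by the CPM given here and in 5 by the effective library sizes of the fit. The direction in clone 10 turned to 0.45 without GFP-negative replicate 3. Sphk2 (ENSMUSG00000057342, chromosome 7, 45709467 to 45718002) ranged from 1.19 to 8.34 CPM, with a change of 0.12 over both clones (SE 0.46) whose sign turned without some libraries. Gene totals can include reads from exons outside the deleted parts, which the labels do not name, so these values neither bear out nor contradict the labels.

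**Figure D1:**
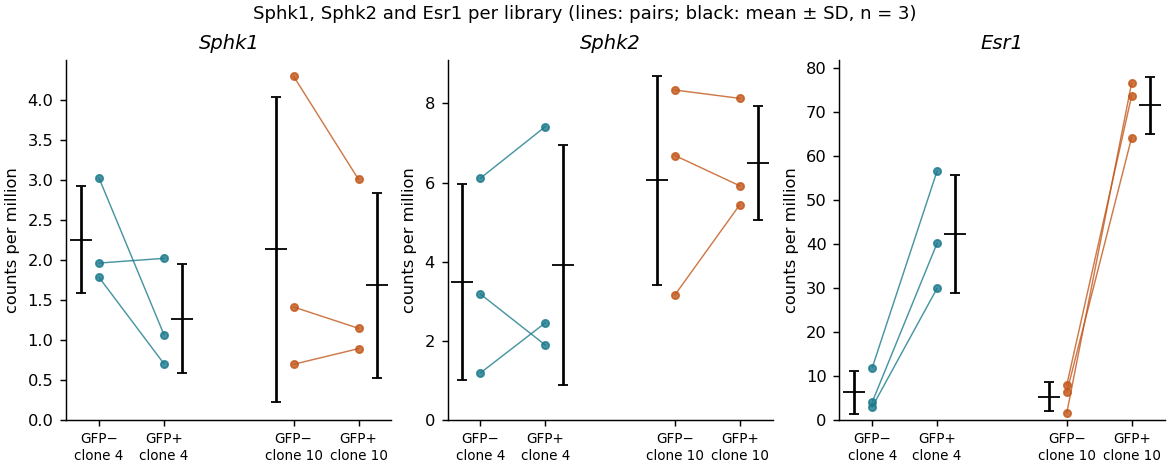
Level in CPM of Sphk1, Sphk2 and Esr1 in each of the 12 libraries, with lines joining the pairs and black marks for the mean and SD of 3 libraries. Esr1 lay between 29.9 and 76.5 CPM in the GFP-positive and between 1.54 and 11.8 CPM in the GFP-negative libraries, whereas the groups overlapped for Sphk1 and Sphk2.

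The first comparison asked what differed between GFP-positive and GFP-negative cells of clone 4. Within pairs, Zscan4c (log2 change 3.24, SE 0.39), Zscan4d (3.37, SE 0.42) and Zfp352 (4.51, SE 0.62), all known from the embryo at the 2-cell stage and from a rare state of embryonic stem cells, were higher in GFP-positive cells, as was Esr1 (2.96, SE 0.38), which encodes estrogen receptor alpha. S100a4 (-2.72, SE 0.38) and Postn (-2.07, SE 0.27), markers of fibroblasts, were lower, with the interferon-inducible Ifi204 (-2.51, SE 0.34) and the metalloproteinase inhibitor gene Timp1 (-0.99, SE 0.13). These were among 18 genes called within pairs, 11 higher and 7 lower, each at an adjusted p of 0.0492. Across all libraries edgeR called 0 of 15179 genes, with 209 at an unadjusted p under 0.05, while DESeq2 called 32 and limma-voom 0. The 209 are a smaller share than the 0.05 that would come with no change at all. The fit without the block, which leaves out the pairs, was thus conservative, and its 0 calls do not show an absence of change. Without any single clone 4 pair the 18 calls fell to 0, and without a clone 10 pair they numbered 207, 57 and 32 for replicates 1, 2 and 3. Of these, 66, 41 and 23 were higher and 141, 16 and 9 lower. With the block, DESeq2 called 88 higher and 92 lower, limma-voom 1 and 5, no filter gave 56 and 42, and only the clone's libraries 53 and 97. The balance of directions in clone 4 was thus not stable.

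Of the 18 measured genes of the two-cell-like list, 6 rose within pairs in clone 4, and 18 did when adjusted over the list alone, with a median of 2.87 (adjusted p = 0.146 with an estimated correlation). Many of these genes have near-identical copies that can share reads, so values of single Zscan4, Usp17l and Tdpoz members are uncertain. Of 23 fibroblast markers 2 fell, and 16 did when adjusted over the list alone, with a median of -1.34 (adjusted p = 0.254 with an estimated correlation). The mean log2 CPM of these markers was lower in the GFP-positive library of each clone 4 pair, at 2.37 against 3.69, 4.13 against 5.42 and 3.42 against 4.68. The interferon response list had a median of -0.29, with 0 of 29 members called, 6 lower when adjusted over the list alone and an adjusted p = 0.146 with an estimated correlation. Members of the G2/M list had a median of 0.32, with 0 of 34 called, 11 higher when adjusted over the list alone and an adjusted p = 0.307 with an estimated correlation. Without any single clone 4 pair, 0 members of these 4 lists were called. Without clone 10 replicate 1, 8 two-cell-like and 5 G2/M genes rose and 16 fibroblast and 7 interferon genes fell, and 4 fibroblast genes fell without clone 10 replicate 2. The 6 two-cell-like calls became 0 with limma-voom and 0 with the stricter filter, and 15 with DESeq2, 12 with no filter and 11 with only the clone's libraries, each with the block. In the authors' deposited table for clone 4, 8 genes were changed at an adjusted p under 0.05, 1 higher (Esr1, 1.57 on the authors' log2 scale) and 7 lower. All 8 had the same sign here and 2 were called within pairs.

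The second comparison put the same question to clone 10. Within pairs, GFP-positive cells had higher Pramef6 (4.93, SE 0.36), Zscan4b (4.81, SE 0.53), Zscan4e (4.52, SE 0.47), Zscan4f (4.37, SE 0.43), Usp17le (4.38, SE 0.50), Usp17la (4.26, SE 0.47) and AF067061 (4.40, SE 0.46), and higher Slc34a2 (4.57, SE 0.51), which encodes a sodium-phosphate cotransporter. Zscan4d went from 21.3 ± 8.0 to 430.3 ± 254 CPM (SD, n = 3 each), against 1.8 ± 1.4 and 24.7 ± 31.9 CPM in clone 4. Pla2g1b, a secreted phospholipase gene, was lower (-1.73, SE 0.24), with the neural factor gene Olig2 (-1.19, SE 0.24), the immunoproteasome subunit gene Psmb10 (-1.16, SE 0.26), the kinase gene Lck (-1.06, SE 0.22), Fgf17 (-1.02, SE 0.20), Hpdl (-1.24, SE 0.23), Dpcr1 (-1.19, SE 0.27) and Tmem98 (-0.97, SE 0.21). Within pairs 641 genes were called, 530 higher and 111 lower. Across all libraries edgeR called 0, with 1131 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0732. DESeq2 called 293 there, 287 higher and 6 lower, and limma-voom 20, all of them higher. With passage as a covariate edgeR called 86, 85 higher and 1 lower. DESeq2 with the block called 970 higher and 601 lower, so the share of falls depended on the fit.

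All 18 measured two-cell-like genes rose within pairs in clone 10, with a median of 3.83 (adjusted p = 0.208 with an estimated correlation). Of 22 histone genes 8 rose, and 14 did when adjusted over the list alone, among them Hist1h4i (2.79, SE 0.30) and Hist1h2bj (2.14, SE 0.35), with a list median of 1.09 (adjusted p = 0.446 with an estimated correlation). Of 32 p53 targets 7 rose, and 14 did when adjusted over the list alone, including the antiproliferative Btg2 (1.12, SE 0.11), Plk2 (1.58, SE 0.27), the proapoptotic Pmaip1 (1.01, SE 0.16) and Mdm2 (0.91, SE 0.16), which encodes the ubiquitin ligase of p53. That list had an adjusted p = 0.446 with an estimated correlation. Germline genes rose in 5 of 22 cases, and in 10 when adjusted over the list alone, with Taf7l at 1.13 (SE 0.14) and Dazl, a germ cell RNA-binding protein gene, at 1.29 (SE 0.21), and the list had an adjusted p = 0.446 with an estimated correlation. Of 42 genes of sphingolipid metabolism 2 rose, the sphingomyelin synthase gene Sgms1 (1.86, SE 0.30) and Sptssb, a small subunit of serine palmitoyltransferase (4.26, SE 0.87), and 5 did when adjusted over the list alone (adjusted p = 0.667 with an estimated correlation). Lin28a (-1.04, SE 0.17) and Nr0b1 (-0.90, SE 0.18) fell and Fbxo15 rose (1.37, SE 0.19) among 27 naive pluripotency genes, where 2 rose and 9 fell when adjusted over the list alone (median -0.34, adjusted p = 0.667 with an estimated correlation). Fibroblast markers were lower in the GFP-positive library of replicates 2 and 3, at 3.93 against 4.80 and 5.19 against 6.05 mean log2 CPM, and higher in that of replicate 1, at 3.40 against 2.303. Their median of -0.41 had no stable direction, at 0.025 without clone 10 replicate 2, 0.040 without replicate 3 and -0.88 without replicate 1.

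The counts of list members called in clone 10 within pairs moved with single pairs. The 8 histone genes became 5, 4 and 2 without clone 4 replicates 1, 2 and 3, and 8, 4 and 1 without clone 10 replicates 1, 2 and 3. The 7 p53 targets became 4 without clone 4 replicate 3 and 3 and 2 without clone 10 replicates 2 and 3, and the 5 germline genes became 0 without clone 10 replicate 3. Fibroblast markers, with 0 called, had 9 lower without clone 10 replicate 1. Two-cell-like genes numbered 16 to 18 over the 6 removals. When only clone 10 libraries were fitted, 2 histone genes, 3 p53 targets, 2 germline genes and 17 two-cell-like genes were called.

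The 641 calls of clone 10 numbered 132 without clone 10 replicate 3, 319 without clone 4 replicate 3 and 266 when only clone 10 libraries were fitted, and 1571 by DESeq2 with the block. Across all libraries, the count of 0 became 100 without clone 4 GFP-positive replicate 1 and 24 without clone 10 GFP-positive replicate 2. In the authors' deposited table for clone 10, 418 genes were changed, 409 higher and 9 lower. Of these, 335 were called within pairs here and 403 had the same sign. Genes not tested here could not count toward the 403, so the remainder need not have the opposite sign.

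**Figure D2:**
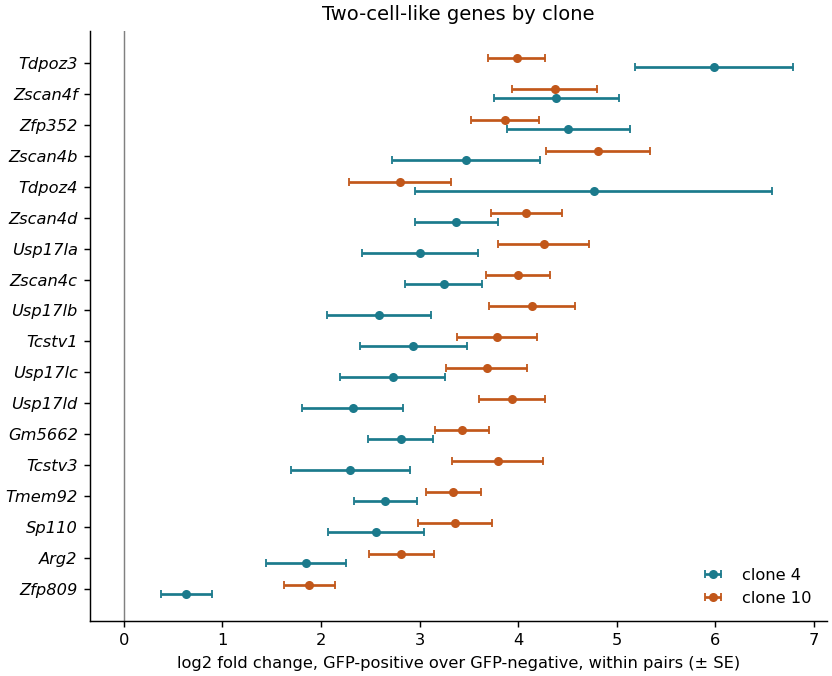
Log2 fold change within pairs of the 18 measured two-cell-like genes in clone 4 and clone 10, with bars for the standard error. Every member lay above 0 in both clones.

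The third comparison took the mean of both clones. Across all libraries 24 genes were called, 23 higher and 1 lower. Esr1 (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614) rose by a log2 change of 3.23 (SE 0.39, adjusted p = 0.0311), from 6.25 to 42.2 CPM in clone 4 and from 5.24 to 71.4 CPM in clone 10, and was higher in 6 of 6 pairs. The other named genes that rose were Zscan4f (4.56, SE 0.63), Zscan4b (4.47, SE 0.61), Zscan4e (4.44, SE 0.57), Zscan4d (3.95, SE 0.66), Usp17le (3.86, SE 0.59), Usp17la (3.81, SE 0.57), the netrin receptor gene Dcc (4.46, SE 0.72), the homeobox gene Lmx1a (3.13, SE 0.53) and the tachykinin receptor gene Tacr3 (2.96, SE 0.44). In clone 4, Dcc stood at only 0.013 CPM in GFP-negative and 0.80 ± 0.93 CPM (SD) in GFP-positive cells. The size of its rise is therefore uncertain. Pla2g1b fell by 1.47 (SE 0.24, adjusted p = 0.0475) and was lower in each of the 6 pairs. DESeq2 called 288 genes and limma-voom 1. The 24 calls fell to 0 without any of 7 libraries, clone 4 GFP-negative replicates 1 and 3, the 3 clone 10 GFP-negative libraries and clone 10 GFP-positive replicates 1 and 3, and to 1 without clone 4 GFP-negative replicate 2. They rose to 76 and 101 without clone 4 GFP-positive replicates 2 and 3, and to 75 without clone 10 GFP-positive replicate 2.

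Within pairs 510 genes were called for the mean of both clones, 381 higher and 129 lower, including all 24 above. Further genes that rose were Tdpoz3 (4.99, SE 0.39), Slc34a2 (4.56, SE 0.58), Zfp352 (4.19, SE 0.34), BC080695 (3.80, SE 0.36), Pramef6 (3.78, SE 0.32) and Pramef17 (3.77, SE 0.66). Tdpoz3, Slc34a2 and Pramef17 stood at only 0.015, 0.017 and 0.071 CPM in clone 4 GFP-negative cells. In clone 4 GFP-positive cells they stood at 1.39 ± 2.21, 0.55 ± 0.85 and 1.78 ± 2.54 CPM (SD). The size of these 3 rises is therefore uncertain. The genes that fell most were Prl2c3 (-2.21, SE 0.30), Pyhin1 (-2.06, SE 0.26), the BMP antagonist gene Grem1 (-1.99, SE 0.37), the smooth muscle actin genes Acta2 (-1.88, SE 0.26) and Actg2 (-1.79, SE 0.25), S100a4 (-1.86, SE 0.26), the growth factor gene Ptn (-1.86, SE 0.31), Mnda (-1.85, SE 0.40), the mast cell protease gene Mcpt8 (-1.74, SE 0.33) and Ifi204 (-1.70, SE 0.24). Without single pairs the 510 calls numbered 125, 257 and 194 for clone 4 replicates 1, 2 and 3, and 980 and 159 for clone 10 replicates 1 and 3, the first of which holds the shallowest library. DESeq2 with the block called 1433.

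By list, 17 of 18 two-cell-like genes rose within pairs, and 18 did when adjusted over the list alone, with a median of 3.36 (adjusted p = 0.197 with an estimated correlation). Across all libraries 4 rose, Zscan4b, Zscan4d, Zscan4f and Usp17la, and 18 did when adjusted over the list alone, with a median of 3.53 (adjusted p = 0.122 with an estimated correlation). Fibroblast markers fell in 6 of 23 cases, and in 14 when adjusted over the list alone, with Postn at -1.58 (SE 0.19), Acta2 at -1.88, Tagln at -1.26 (SE 0.17) and S100a4 at -1.86, and had a median of -0.84 (adjusted p = 0.726 with an estimated correlation). Of 29 interferon response genes 6 fell, and 13 did when adjusted over the list alone, with the immunoproteasome subunit gene Psmb8 at -1.16 (SE 0.15), Ifit3 at -1.40 (SE 0.24), B2m at -0.76 (SE 0.15) and Isg15 at -0.60 (SE 0.12), and an adjusted p = 0.228 with an estimated correlation. Of 32 p53 targets 6 rose, and 13 did when adjusted over the list alone, with Btg2 at 0.65 (SE 0.08) and Trp53inp1 at 0.84 (SE 0.14), and an adjusted p = 0.481 with an estimated correlation. Of 34 G2/M genes 6 rose, and 17 did when adjusted over the list alone, with Hmmr at 0.76 (SE 0.11) and Prc1, a midzone spindle protein gene, at 0.51 (SE 0.09), and an adjusted p = 0.726 with an estimated correlation. Of 22 germline genes 6 rose, and 13 did when adjusted over the list alone, with Sycp1, a synaptonemal complex gene, at 1.25 (SE 0.19), and an adjusted p = 0.308 with an estimated correlation. Single pairs moved most of these counts, while 15 to 18 two-cell-like genes rose within pairs over the 6 removals. Without clone 10 replicate 1, which holds the shallowest library, 17 fibroblast markers and 13 interferon response genes fell and 10 p53 targets and 12 G2/M genes rose. Interferon response genes numbered 1, 1 and 3 without clone 4 replicates 1, 2 and 3, and 3 and 1 without clone 10 replicates 2 and 3. Without clone 4 replicates 1, 2 and 3, the p53 targets numbered 1, 6 and 1, the G2/M genes 1, 2 and 1 and the germline genes 0, 4 and 2. Without clone 10 replicate 3 they numbered 3, 1 and 0.

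Genes of sphingolipid metabolism had a median of 0.13, and 1 of 42 rose within pairs, Sgms1 (1.13, SE 0.21), which was also the count when adjusted over the list alone. Of the 5 measured receptors of sphingosine 1-phosphate 0 were called and 1 was lower when adjusted over the list alone. All 31 genes of oxidative phosphorylation had a negative estimate, with a median of -0.25, 0 calls over all genes or over the list alone, and an adjusted p = 0.727 with an estimated correlation.

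**Figure D3:**
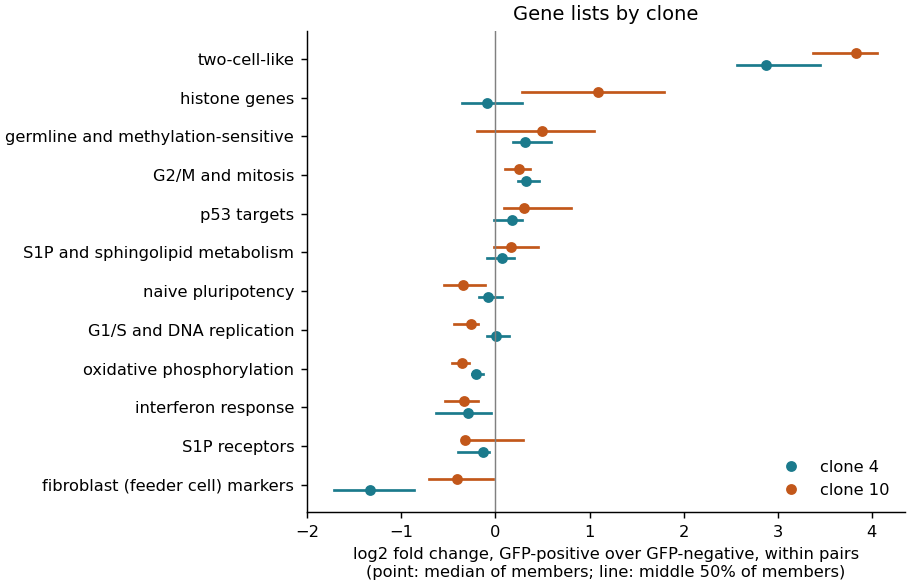
Median log2 fold change within pairs of the members of 12 gene lists in each clone, with lines over the middle 50% of members. The two-cell-like list lay at 2.87 in clone 4 and 3.83 in clone 10, and the fibroblast list at -1.34 and -0.41, the last of which turned to 0.025 and 0.040 without clone 10 replicates 2 and 3.

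Both clones were then set side by side. Across 15179 genes, which are not independent replicates, the log2 changes of clone 4 and clone 10 had a Pearson correlation of 0.637 and a Spearman correlation of 0.520, and 69.2% had the same sign. No library was shared by the comparisons. Within pairs, 11 genes were higher in both clones, where independent lists would share 0.384, 3 were lower in both, where 0.0512 would be shared, and 0 were called with opposite signs. The lists came from a single fit with a shared spread per gene, and libraries of the clones varied together. The numbers for independent lists are therefore not a chance level. Among the 11 were Esr1, Zscan4c, Zscan4d, Zfp352, Tdpoz3 and Tmem92, and the 3 included Timp1 and Anxa2, which were chosen by this overlap. A test of the difference between the clones called 0 genes, with 140 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. The 140 are a smaller share than the 0.05 that would come with no difference. That test was thus conservative, and its 0 calls do not show equal effects. Within pairs it called 0 with 1167 at an unadjusted p under 0.05, 62 by DESeq2 and 0 by limma-voom. For Esr1 the difference was 0.90 (95% interval -0.69 to 2.49), and for Sphk1 0.42 (-1.56 to 2.40).

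**Figure D4:**
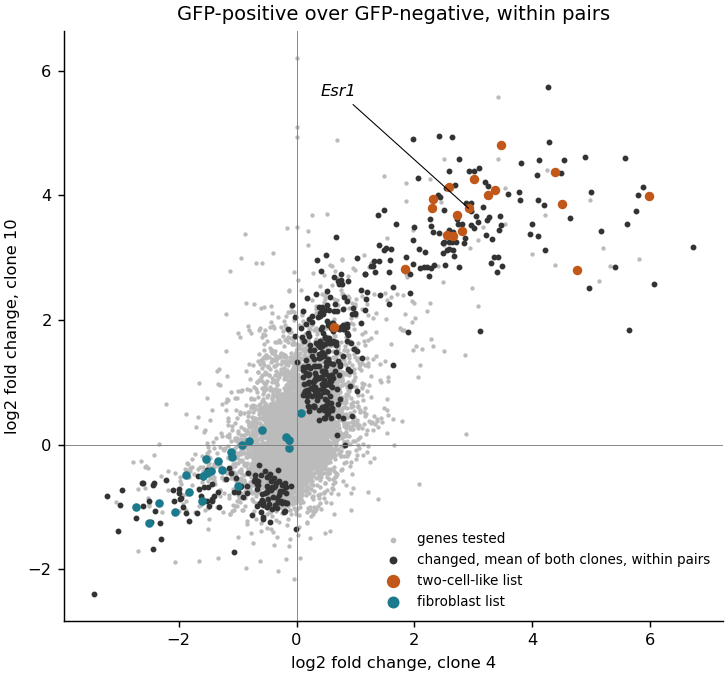
Log2 fold change within pairs of each of 15179 genes in clone 4 (horizontal) and clone 10 (vertical), with the 510 genes changed for the mean of both clones in black, two-cell-like genes in orange and fibroblast markers in blue. Two-cell-like genes lay high in both clones, and fibroblast markers had a median of -1.34 in clone 4 and one in clone 10 whose sign depended on single pairs.

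The last comparison set GFP-negative cells of clone 10 against those of clone 4, as a measure of how far clones of the same stated genotype differ. Genes higher in clone 10 were the serine protease gene Tmprss5 (5.66, SE 0.76), the serpin gene Serpinb6c (2.54, SE 0.36), Rassf4 (2.52, SE 0.37), Mid1ip1 (1.64, SE 0.21), the matrix protein gene Smoc1 (1.60, SE 0.23) and Mapt (1.34), which encodes tau and was named because so few genes were called. Rbm44, an RNA-binding protein gene, was lower (-2.38, SE 0.30). Mid1ip1 stood at 33.7 ± 4.8 CPM in clone 4 and 92.8 ± 5.9 CPM in clone 10 (SD, n = 3 each), and Rbm44 at 37.8 ± 10.0 and 6.5 ± 1.2 CPM. These 7 genes were called by edgeR at adjusted p values from 0.0293 to 0.0447, against 402 by DESeq2 and 11 by limma-voom. With only the 6 GFP-negative libraries the count was 0, and it was 0 to 19 when single libraries were left out, 19 without clone 4 GFP-positive replicate 1, 2 without clone 10 GFP-negative replicate 1, 7 without clone 4 GFP-positive replicate 2 and 0 without any of the other 9. Deviations of the libraries matched between the clones, number 1 with 1 and numbers 2 and 3 crossed, and a block by that matching called 1737 genes, 874 higher and 863 lower. The matching was read from the same counts and the labels do not give it, so this count is an alternative and not a result in its own right.

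In GFP-negative cells two-cell-like genes had a median of 3.55 in clone 10 over clone 4, with 0 of 18 called over all genes and 17 when adjusted over the list alone (adjusted p = 0.315 with an estimated correlation). Zscan4d was at 3.77 (SE 0.94), and Dcc, Lmx1a and Tacr3 at 6.06 (SE 1.22), 2.92 (SE 0.78) and 3.11 (SE 0.66), while Esr1 was at -0.10 (SE 0.52), none of them called. Dcc stood at only 0.013 CPM in GFP-negative cells of clone 4, so the size of its difference is uncertain. Naive pluripotency genes had a median of 0.53 with 0 of 27 called, over all genes or over the list alone (adjusted p = 0.364 with an estimated correlation). Integrated stress response genes had a median of 0.45 with 0 of 38 called and 1 when adjusted over the list alone (adjusted p = 0.826 with an estimated correlation).

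Genes of whole chromosomes also differed in level between the clones, a comparison chosen after the values were seen. Among genes with an average log2 CPM of at least 3, those of chromosomes 5, 8, 11 and 19 had medians from -0.23 to -0.17 in clone 10 against clone 4. The other 15 autosomes had medians from 0.10 to 0.27. The gap between the medians of both sets, of 2533 and 7524 genes, was -0.37. GFP-positive against GFP-negative cells had chromosome medians of at most 0.098 in size in clone 4 and 0.165 in clone 10. Sphk1 and Acta2 lie on chromosomes 11 and 19 of this set, Pla2g1b and Slc34a2 on 5 and Psmb10 on 8.

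**Figure D5:**
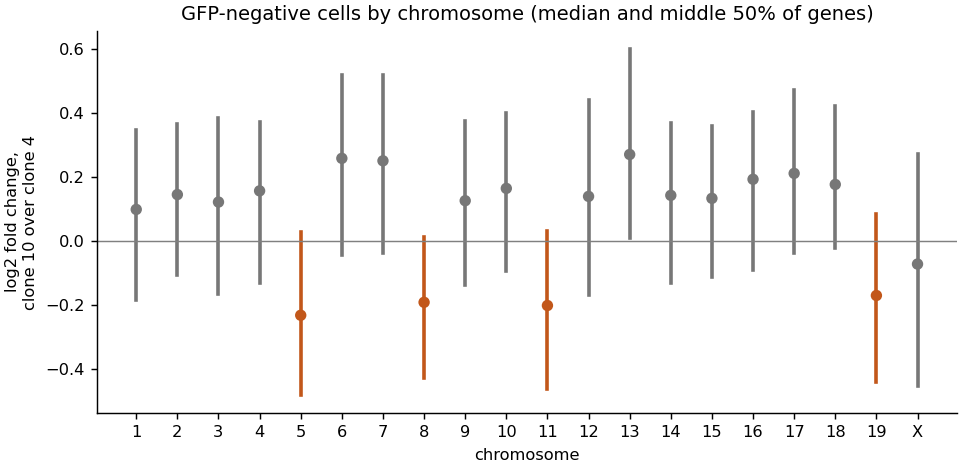
Median log2 fold change of genes by chromosome, GFP-negative clone 10 over GFP-negative clone 4, with lines over the middle 50% of genes. Chromosomes 5, 8, 11 and 19, in orange, had medians from -0.23 to -0.17 and every other autosome one from 0.10 to 0.27.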

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

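The tests of shared reads, single pairs, fibroblast-like cells, passage, Sphk1 loss and Esr1 described in this part were chosen only after the results were seen, while the counts over other splits of the libraries were planned, except those over splits within pairs for the fit across all libraries. The effect of the GFP gate on 14 gene lists differed between the clones by camera on the interaction, at the preset correlation, and none of the 14 kept its call with an estimated correlation (adjusted p from 0.279 to 0.857). Groups of 3 libraries were not tested for single outlying libraries. Each value is the median over members of the log2 change in clone 10 minus that in clone 4, across all libraries.

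The difference was 1.26 for histone genes, with medians of 0.97 in clone 10 and -0.11 in clone 4. Trophoblast genes differed by 0.73 and fibroblast markers by 0.61, the latter with medians of -0.73 in clone 10 and -1.38 in clone 4. Two-cell-like genes differed by 0.58, with medians of 3.93 and 3.22 that point the same way. Immediate early genes differed by 0.45, imprinted genes by 0.33, p53 targets by 0.22, genes of lysosome and autophagy by 0.19 and genes of sphingolipid metabolism by 0.0822. Lists with a lower change in clone 10 were those of G1/S and DNA replication (-0.32), naive pluripotency (-0.28), cholesterol synthesis (-0.26), oxidative phosphorylation (-0.23) and fatty acid synthesis (-0.19).

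The rise of two-cell-like genes in GFP-positive cells was weighed first. Reads shared between copies of a gene family do not account for all of it. The 3 members with at least 95% unique sequence, Arg2, Tmem92 and Zfp809, had a median log2 change of 2.33, and all 3 were called within pairs. The other 15 members had a median of 3.62 and a minimum of 2.96, against a minimum of 1.26 for these 3. An effect of shared reads on the size of the rise is therefore not excluded. A single pair of libraries did not carry it, as the lowest median over the 6 removals of a pair was 3.05, and fewer fibroblast-like cells among the GFP-positive cells would raise other stem cell genes alike, whereas naive pluripotency genes had a median of -0.19. GFP-positive libraries were labelled 1 passage later in 5 of 6 pairs. The labels of replicates 2 and 3 rose by 1 from each sample to the next across clones and gates, so they may not be true passages. Only if taken as given do they argue against a steady effect of passage. The mean log2 CPM of the list over the 6 pairs within clones changed by -0.22 per passage (95% interval up to 0.194), far under the median rise of 3.36. In the pair of equal passage it rose by 3.50. Loss of Sphk1 and activity of Cre, or the gate itself, cannot be told apart, because 0 of the GFP-positive libraries keep the floxed Sphk1 by their labels. The rise may therefore follow from any of these.

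The rise of Esr1 was weighed next. If Esr1 followed the two-cell-like list, it might also be higher in GFP-negative cells of clone 10, where that list had a median of 3.55. No member of the list was called there, and the 95% interval of Esr1 reached only 1.04. This compares clones and not gates, so it does not settle whether Esr1 is part of the two-cell-like rise within clones. The 6 genes tested within 500 kb of Esr1 had a median log2 change of 0.11 within pairs, and every GFP-positive library lay above every GFP-negative one. Reads of a Cre fused to part of the estrogen receptor, as used in tamoxifen-inducible systems, may be counted on Esr1. They would leave its neighbours in place, but so could a rise of Esr1 transcripts alone. The neighbours therefore do not tell these apart, and the rule that named Esr1 in clone 4 had itself asked for no overlap. The fusion remains a hypothesis, since the labels do not name the construct. No other biological explanation of the rise of Esr1 was tested.

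The numbers of genes called were compared with other splits of the same libraries. For the mean of both clones, 24 genes were called across all libraries. The real split parts all 6 pairs, and among the 32 splits that do so the other 31 called 0 genes at most. Only 1 split, the real one, gave as many, a share of 0.03125. No smaller share is possible with 32 splits, so chance is less likely but not excluded. Of 100 splits drawn from 200, 86 parted fewer pairs, and at most 5 genes were called in those other than the real one. Within pairs, 510 genes were called. At most 19 were called in the other 31 of 32 splits that swap libraries within pairs and so part as many pairs. The share was again 0.03125, with the same limit. Across all libraries, clone 4, clone 10 and the difference between clones each gave 0 genes in the real split and in all 10 splits, and clone 10 against clone 4 gave 7 against 0 at most. Within pairs, clone 4 gave 18 and clone 10 gave 641, with 0 at most in the other splits. With 10 or 4 splits the splits are too few for a share under 0.05.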

How the results depend on the processing

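The changes made to the fit within pairs, the block by matching between clones, the removal of whole pairs and the fibroblast score were chosen only after the data were seen, and the other alternatives were planned. Where a count moved, the cause was not tested unless stated.

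In place of edgeR across all libraries, DESeq2 called 32 genes for clone 4, 293 for clone 10, 288 for the mean of both clones and 402 for clone 10 against clone 4, and limma-voom called 0, 20, 1 and 11. Without a filter on low counts 0, 6, 67 and 4 were called, with the stricter filter 10 for the mean, and with passage as a covariate 0, 86, 138 and 22. Clone 10 against clone 4 gave 0 with only the libraries of the comparison. DESeq2 size factors and a minimum change of 2-fold left each count within 1.5 times its value, and the difference between clones stayed at 0 throughout. Leaving out each library in turn gave 0 genes for clone 4 in every case, 0 to 100 for clone 10, 0 to 101 for the mean, and 0 to 19 for clone 10 against clone 4.

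The replicate block raised the counts to 18 for clone 4, 641 for clone 10 and 510 for the mean. For clone 10 against clone 4, a block by number gave 136, although only number 1 varied with its own number in the other clone. A block by the libraries that varied together (1 with 1, 2 and 3 crossed) gave 1737, and 11 lists by camera. With the block, 233 of the 288 genes that DESeq2 called for the mean without it were called by edgeR, 263 of 293 for clone 10 and 4 of 32 for clone 4. Camera called 10, 14, 12 and 14 lists for clone 4, clone 10, the mean and the difference with the block.

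Within pairs, DESeq2 with the replicate block called 180, 1571 and 1433 genes for clone 4, clone 10 and the mean, and 62 for the difference between clones. For clone 4 the 18 calls became 6 with limma-voom, 98 with no filter, 0 with the stricter filter and 150 with only the clone's libraries, and for clone 10 the 641 became 266 with only its libraries. A fibroblast marker score as a covariate gave 2285, 5003, 5327 and 1 for the difference, but it was taken from the same counts and left 3 residual degrees of freedom, so these were not read as further changes. Removing pairs gave 0 to 207 for clone 4, 132 to 657 for clone 10, 125 to 980 for the mean and 0 to 1 for the difference. Without clone 10 GFP-negative replicate 1, the shallowest library, the mean gave 0 genes across all libraries. With its partner also left out, the mean gave 980 within pairs.

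With the preset correlation camera called 9, 10, 11, 14 and 11 lists for clone 4, clone 10, the mean, the difference and clone 10 against clone 4. An estimated correlation gave 0 in each, and fry 0, 1, 1, 0 and 1, or 0, 4, 5 and 0 for the first 4 within pairs. Leaving out libraries gave 7 to 11, 8 to 11, 7 to 13, 5 to 17 and 10 to 13. The correlation of the clones' changes was 0.637, 0.759 among genes at a log2 CPM of at least 3 and 0.635 with size factors.

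Gene values that changed sign were those of Sphk1 and Sphk2, neither of them called. Within pairs, the fibroblast median changed sign in clone 10 without replicate 2 or 3 (0.025 and 0.040) and, in each clone and the mean, with its own score as a covariate. Sphk1 in clone 10 ranged from -1.07 to 0.45 over the removals, with 0.45 without clone 10 GFP-negative replicate 3. Sphk2 in clone 4 was -0.18 without GFP-negative replicate 1 and -0.70 without GFP-positive replicate 3 (range -0.70 to 0.95). Sphk2 in clone 10 was -0.0467 with passage, and -0.24 without GFP-negative replicate 1 or GFP-positive replicate 2 (range -0.24 to 0.33). For the mean it was -0.08 and -0.34 without those clone 4 libraries and -0.01 without clone 10 GFP-positive replicate 2 (range -0.34 to 0.48). Genes named from the fit across all libraries gave 17 fold changes over the comparisons, and of their 335 values under alternatives 163 stayed past the threshold, 172 did not and 0 changed sign. Those named from the fit within pairs gave 44, and of 550 values 447 stayed past it, 103 did not and 0 changed sign. Depth limits what can be said of genes near 1 CPM such as Sphk1.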

Other observations

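The tests of single libraries in the chromosome comparison, the chromosome comparison itself and the choice of Ddit3 came only after the results were seen, while the fit on GC content and the test by parts of a chromosome were set before their own results. Other lists had single members that changed in GFP-positive cells for the mean of both clones within pairs. Cyclin D2 (Ccnd2) fell by 1.47 (SE 0.21) and the cell cycle inhibitor gene Cdkn2a by 0.60 (SE 0.09), 2 of 14 genes of cell cycle exit, where 2 rose and 4 fell when adjusted over the list alone. Among 19 genes of formative and primed pluripotency, Nodal (0.53, SE 0.09), Cldn6 (0.61, SE 0.12) and Sox3 (0.78, SE 0.17) rose and Foxd3 fell by 0.57 (SE 0.11), and 4 rose and 4 fell when adjusted over the list alone. Single genes of other lists rose, namely the epithelial-mesenchymal transition factor gene Snai1 (0.97, SE 0.15), the forkhead gene Foxa1 (1.22, SE 0.23), Traf1 (1.26, SE 0.14), the collagen prolyl hydroxylase gene P4ha2 (1.27, SE 0.15) and Gpnmb (1.27, SE 0.21). Of the stress response genes, Chac1 (-0.65, SE 0.12) and Asns (-0.58, SE 0.13) fell, 2 of 38, with 3 higher and 3 lower when adjusted over the list alone. Of the 381 genes that rose, 63 had only predicted or clone names, against 2 of the 129 that fell.

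Ddit3, the stress-induced transcription factor gene known as CHOP, stood at 226 CPM in GFP-negative and 216 CPM in GFP-positive replicate 2 of clone 4. The other clone 4 libraries lay between 7.09 and 20.0 CPM and the clone 10 libraries between 25.5 and 47.3 CPM. Both libraries of that pair thus stood apart from the rest in the same way, whatever their gate.

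Genes of chromosomes 5, 8, 11 and 19 were lower in clone 10 than in clone 4, with a gap to the other autosomes of -0.37 on the log2 scale in GFP-negative cells and -0.36 over all libraries. A fit on GC content and gene length, which covered 99.7% of the genes, left a gap of -0.36, and the smallest gap over the 12 removals of a library was -0.36, so neither GC content, length nor a single library accounts for it. In single libraries, the median of these chromosomes minus that of the others was 0.16 to 0.21 in clone 4 and -0.22 to -0.13 in clone 10. Each of these chromosomes was also divided at its middle gene, and 8 of 8 parts had a median below the lowest of the other autosomes. These chromosomes were chosen for their low medians, so low parts were likely from the start. The parts show only that the shift was present on both sides of the middle gene. A difference in the copy number of whole chromosomes in part of the cells is a candidate explanation and remains a hypothesis. It allows either direction, and 3 copies against 2 in all cells would give 0.585. Gains of chromosomes 8 and 11 are known to recur in cultured mouse embryonic stem cells. Expression alone does not tell which clone departed from the usual number.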
